A study of Danio rerio with 3 samples.

How the data were processed

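RNA from whole zebrafish embryos was compared on a 2-colour Agilent oligonucleotide array that carries 45220 features. Per the labels' protocols, total RNA was taken with a column kit, and 2 µg from exposed and from control embryos was amplified and labelled with Cy3 and Cy5. There were 3 arrays, 1 for each biological replicate, and each held control RNA in channel 1 and exposed RNA in channel 2. All 3 arrays form a single group, in which each ratio already sets exposed against control embryos. The design names dye swaps, and how dye-swapped hybridisations were combined is not given in the sources used here.

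The deposited table holds 1 signed value per feature and array, taken here as the log2 ratio of the channels. The base of the logarithm, the direction of the ratio, the background correction, the normalization and the filter on dim spots are not given in the sources used here. If the base were 10, the stated fold sizes would be larger, and the tests would stay as they are apart from the 2-fold threshold. The columns were not centred at exactly 0: over the named features that were tested, the medians were -0.14, -0.02 and -0.05 on arrays 1, 2 and 3, and over all features with a value -0.07, -0.01 and -0.02. The spreads of the named features differed too, with SDs of 0.745, 0.476 and 0.810. All 3 columns of values were used, and 0 columns were left aside. No intensities were used here, so signal over background is unknown and the number of arrays limits the precision.

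A value was present on all 3 arrays for 13895 features, on 1 or 2 arrays for 2002, and on none for 29323. In the platform's annotation 21061 features had 1 gene symbol, 0 had several, and 24159 had none and stayed unnamed. Of the platform's 14504 gene identifiers, 13771 were found in the RefSeq gene table of assembly GRCz12tu, and 0 of these carried another symbol there. The platform names no genome build, so no coordinates are printed.

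The deposited row number could not be used as the platform's feature number. Among 3952 genes with exactly 2 features, the features of a pair had unrelated log ratios under those numbers, with a mean r over the 3 arrays of -0.01 across 371 pairs. The rows were therefore tested against 42 orders in which a scanner could read the array grid. One order, by columns of the staggered grid turned upside down, gave r = 0.748, 0.492 and 0.464 on the 3 arrays across 1420 pairs, with a mean of 0.568. The mean r of the other 41 orders lay between -0.065 and 0.065, and the highest of 1000 draws of random pairs was 0.057. Every circular shift of 6 simple orders was also scored by where values were present, and the best phi coefficient among 271320 shifts was 0.074, against 0.445 for the order used. Under that order 80.5% of 133 ribosomal protein features had values, and 48.1% of named features against 15.6% of unnamed ones. The order was chosen after the data were seen, from agreement within arrays and not from any list, gene or test. All gene names rest on it. Under the deposited numbers no feature, gene or list passed, while 16 genes were at least 2-fold the same way on all 3 arrays, against 21.

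The main setting kept features with a value on all 3 arrays and a gene symbol, with values as deposited: 10120 features of 7507 genes. A gene's value on an array was the mean over its features. 5419 genes rested on 1 feature and 2088 on several. Each feature and gene was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, intercept only, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 32 lists with at least 5 measured members. Camera with an estimated correlation and fry, which does not compare a list with other genes, were run beside it. With an estimated correlation camera takes its degrees of freedom from the arrays. On 3 arrays a list could therefore hardly pass it after adjustment. The tests, the lists, the rule for named genes and the first set of alternatives were fixed before the data were examined.

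The rule for named genes took the 12 genes of each sign with the largest mean among those past the threshold with the same sign on all 3 arrays. Where fewer passed, the places were filled by smallest p and are given as values that did not pass. Symbols of clones, loci and predicted genes were left out. Up to 4 members of each list with the smallest p could also be named, and ache, cyp1a, hsp70l, hmox1a, gstp1.1 and fkbp5 wherever measured. The name hmox1a is not among the platform's symbols. List members were matched by exact symbol: of 1271 genes in the lists, 976 were on the platform and 702 had values.

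The tests were tried on simulated arrays with the variance of these data, 7507 genes and 200 changed genes in 20 runs. Of genes changed by 1 on the log2 scale 9.5% were recovered, of those changed by 2 90.4%, by 3 98.6% and by 4 100%. Genes that had not been changed made up 4.86% of calls on average. A shift of 0.5 in the ribosome list was recovered in 100% of runs. These simulated arrays shared one spread and had no correlation between genes, so they describe a simpler case than the real arrays.

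Alternatives covered centring, scaling, quantile normalization, a value on at least 2 arrays, each array left out in turn, a robust and an ordinary variance, the rule for several features of a gene, a threshold of 0.1, and other settings of camera. Figures and layout tests used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.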

Results

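Zebrafish embryos were exposed to chlorpyrifos, an organophosphate insecticide that inhibits acetylcholinesterase once it is converted to its oxon, and were compared with embryos kept in fish medium. Exposure to 7 mg/L began at 24 h post fertilisation (hpf) and lasted 24 h at 28.5 °C, and whole embryos were taken at 48 hpf. Each of 3 biological replicates gave 1 array of log2 ratios between exposed and control RNA, with 10120 named features of 7507 genes measured on all 3 arrays. The comparison asks which genes differed between exposed and control embryos. Both channels are listed with both dyes, so the labels do not settle which way the ratio runs. Values are given as positive or negative deposited log2 ratios, and neither sign is read as higher or lower in exposed embryos. The arrays were taken to run the same way, since each pair correlated above 0 over the named features (Pearson r = 0.175, 0.175 and 0.302). These correlations are across features, which are not independent replicates. An effect of the dyes that repeats across arrays would raise them too. Because the handling of dye swaps is not given, it cannot be told apart from an effect of exposure.

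Gene names depend on a re-reading of the row numbers. Under the deposited numbers, features of the same gene had a mean r of -0.01, and under the order used here 0.568.

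**Figure D1:**
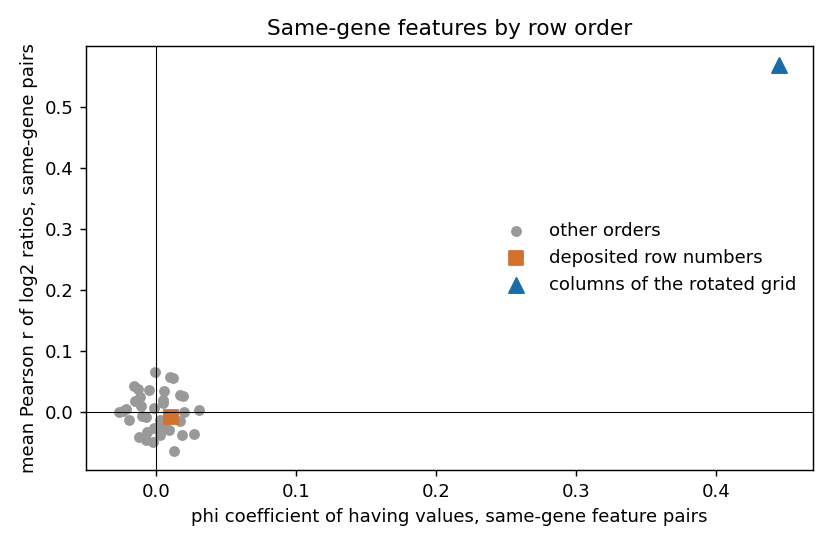
Each point is 1 of 42 orders in which the rows of the deposited table were matched to array features. The x axis is the phi coefficient of having values in pairs of features of the same gene and the y axis is the mean Pearson r of their log2 ratios over the 3 arrays, both without units. The order used lies at 0.445 and 0.568, and the deposited row numbers lie at 0.011 and -0.01 among the other orders.

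The gene agxtb (NCBI gene 79378), which encodes an alanine-glyoxylate aminotransferase, had a mean log2 ratio of -4.36 ± 1.08 (SD, n = 3) and was negative on all 3 arrays. It was the 1 gene of 7507 that passed (limma, adjusted p = 0.0289), and it was past 2-fold. On the positive side cyp1a (NCBI gene 140634), the cytochrome P450 monooxygenase controlled by the aryl hydrocarbon receptor (AhR), had a mean of 3.57 ± 1.32 (SD, n = 3), with 3.04, 2.60 and 5.08 on the 3 arrays. It did not pass at the level of genes (limma adjusted p = 0.0662), though it did without replicate 2 (limma adjusted p = 0.00414) and without replicate 3 (limma adjusted p = 0.00159). In limma no gene passed without replicate 1, 5 passed without replicate 2 and 13 without replicate 3. With 2 arrays left, a gene's own variance has 1 degree of freedom, so limma leans mostly on the variance pooled over all genes. Such calls are therefore no firmer than those on 3 arrays.

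Of 10120 single features, 6 passed adjusted p 0.05 in limma, 1 positive and 5 negative. The positive one was the feature of cyp1a (limma adjusted p = 0.0491). The negative ones were the feature of agxtb, both features of fkbp5, and 1 feature each of gc and rhcga. The gene fkbp5 encodes a co-chaperone of steroid receptors that glucocorticoids induce, and its features had means of -2.61 and -2.30. The gene gc encodes the vitamin D-binding protein of plasma and had a mean of -2.85 ± 0.87 (SD, n = 3). The gene rhcga encodes an ammonium transporter and had -2.27 ± 0.44 (SD, n = 3). Averaged by gene, fkbp5, gc and rhcga had the same adjusted p as cyp1a, and so did dennd2db with a mean of -2.09 ± 0.39 (SD, n = 3). Together with agxtb these are the 6 genes under an adjusted p of 0.1, of which 1 was positive. Without replicate 1 no feature passed, and 82 did without replicate 2 and 88 without replicate 3. These fits on 2 arrays leaned on the pooled variance as well. After centring of each array 1 feature passed, and 3 did after quantile normalization. None of the 6 passed with the ordinary one-sample test, which could hardly pass any of 10120 features for want of degrees of freedom. Nor did any pass when the 13895 features with a value on all 3 arrays, named or not, were tested together. With a value on at least 2 arrays 1 feature passed, and after centring and scaling 1.

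Other genes with the same sign on all 3 arrays did not pass and are given as values. The largest positive mean among those the rule named was that of anxa1b, an annexin that binds phospholipids in a calcium-dependent way, at 3.88 ± 2.15 (SD, n = 3). Its 3 features had near-equal values on each array, around a gene mean of 6.01, 3.92 and 1.71, so the spread lay between arrays. Without replicate 3 the gene passed (limma adjusted p = 4.34e-05), a call that rests mostly on the pooled variance. The tubulin-binding gene tppp3 had a mean of 1.80 from 1 feature, with 2.36, 1.70 and 1.35 on the 3 arrays. Its other feature was smaller, with 0.72 and 0.99 on arrays 1 and 2 and no value on array 3. The embryonic beta globin hbbe3 had a mean of 1.92. The somatostatin gene sst1.1 had 1.25, the angiotensinogen gene agt 1.45, mala.2 2.21, and sec61g, a subunit of the endoplasmic reticulum translocon, 1.99. On the negative side stood klf11a, a Krüppel-like transcription factor, with -1.79 ± 0.25 (SD, n = 3), and slc16a12b, of the monocarboxylate transporter family, with -1.85 ± 0.45 (SD, n = 3). Further negative means were those of pfkfb4b, which sets the level of fructose 2,6-bisphosphate (-1.64), and of cetp, the cholesteryl ester transfer protein (-1.65). The prothrombin gene f2 had -1.34, the lanosterol synthase gene lss -1.40, and mylipa, a ubiquitin ligase of lipoprotein receptors, -1.43.

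**Figure D2:**
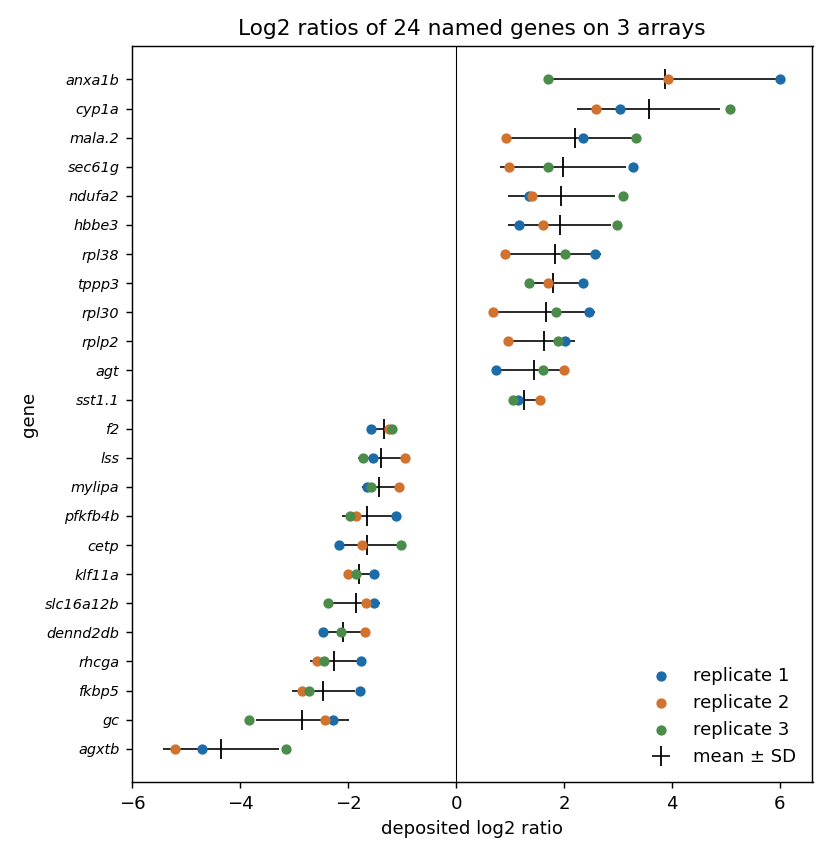
Deposited log2 ratios (x axis) of the 24 genes named by rule (y axis), with 1 coloured point per biological replicate and a black line for the mean ± SD of the 3 arrays. All 24 genes keep 1 sign on the 3 arrays, and the means run from -4.36 for agxtb to 3.88 for anxa1b.

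At least 2-fold on every array and the same way, there were 21 genes, 7 positive and 14 negative. After each array was centred on its median the split was 12 positive and 10 negative, and after centring and scaling 20 and 11. With the rule applied to 2 arrays, 76 genes met it without replicate 1, 144 without replicate 2 and 55 without replicate 3. Of all genes 36.8% had the same sign on the 3 arrays, where 25% follow from chance alone, with 1065 positive and 1695 negative. At an unadjusted p under 0.05 there were 827 genes, 355 positive and 472 negative, where 375 would be found by chance. The median of the named features lay below 0 on each array, which by itself favours negative signs. These splits by sign were not recounted after centring. The target enzyme of the insecticide, ache, had 1 feature and the glutathione transferase gene gstp1.1 had 5, none of them with values, so neither was measured here. The heat-inducible hsp70l had -0.41, 0.61 and 2.17 on the 3 arrays.

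Among 32 gene lists, 7 passed camera with the preset correlation, 6 positive and 1 negative. None passed with an estimated correlation, where each of the 7 had an adjusted p = 0.831. On 3 arrays that test has too few degrees of freedom for a list to pass readily. It therefore cannot tell whether correlation between genes undid the calls. For Nrf2 the estimated correlation was -0.025, below the preset 0.01, yet the camera p rose from 0.00137 to 0.0715. The split by sign depended on the arrays: 6 lists passed without replicate 2, all positive, and 9 without replicate 3, 4 positive and 5 negative, of which 5 are among the 7. After centring and scaling 8 passed, 5 positive and 3 negative. In fry, which asks whether the members of a list move one way, no list passed (smallest adjusted p = 0.214). That test also has few degrees of freedom on 3 arrays, so its outcome says little against the lists. In the mixed test of fry, for changes in either direction, 2 passed, liver (fry adjusted p = 0.0117) and lipid transport and cholesterol (fry adjusted p = 0.0466). No member of any list passed over all genes in limma (119 of 702 measured members had an unadjusted p under 0.05), and 24 entries in 13 lists passed adjusted over the list alone. The ribosomal protein genes had a median log2 ratio of 0.52 over 65 measured members (camera adjusted p = 8.87e-14, and adjusted p = 0.831 with an estimated correlation), with 61 positive means and 4 negative. Their medians were 0.89, 0.18 and 0.35 on the 3 arrays. Adjusted over the list alone 3 passed, rplp2 at 1.62 ± 0.57, rpl38 at 1.84 ± 0.84 and rpl30 at 1.67 ± 0.90 (SD, n = 3), all positive. The subunits of mitochondrial respiration had a median of 0.28 over 48 members, 34 of them positive (camera adjusted p = 0.000624, and adjusted p = 0.831 with an estimated correlation). Its medians were 0.19, 0.01 and 0.40 on the 3 arrays. Adjusted over the list alone the complex I gene ndufa2 passed, with a mean of 1.95 ± 0.99 (SD, n = 3). Other short mRNAs outside both lists, a set chosen after these values were seen, had a median of 0.41, with 49 of 61 genes positive.

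The list of Nrf2 targets and oxidative stress genes had a median of 0.22 over 23 members, 15 positive and 8 negative (camera adjusted p = 0.0138, and adjusted p = 0.831 with an estimated correlation), and medians of 0.29, 0.19 and 0.11 on the 3 arrays. Adjusted over the list alone 2 passed, both positive. They were nfe2l2a, which encodes the transcription factor Nrf2 itself, at 1.103 ± 0.03, and the ferritin heavy chain gene fthl27 at 1.18 ± 0.60 (SD, n = 3). The small SD of nfe2l2a arose from averaging 2 features whose differences between arrays cancelled. One feature had 1.42, 0.84 and 0.95 on the 3 arrays, and the other 0.82, 1.40 and 1.19. The superoxide dismutase gene sod1 had 1.06 and did not pass. Without replicate 1 the adjusted p of this list was 0.0711. The heat shock list had a median of 0.52 over 19 members, 13 positive (camera adjusted p = 0.0138, and adjusted p = 0.831 with an estimated correlation), with no member past the threshold over the list alone. Its medians were -0.25, 0.17 and 1.297 on the 3 arrays, and without replicate 3 the adjusted p was 0.703. The mitochondrial co-chaperonin hspe1 had a mean of 1.21 and the heat shock factor gene hsf2 0.98.

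The liver list was the 1 negative list that passed, with a median of -0.30 over 22 members, 19 negative and 3 positive (camera adjusted p = 0.0406, and adjusted p = 0.831 with an estimated correlation). Its medians were -0.57, -0.41 and 0.08 on the 3 arrays. Adjusted over the list alone gc and f2 passed, both negative. One feature of f2 had -2.31, -1.91 and -1.20 on the 3 arrays, and the other -0.86, -0.57 and -1.19. Their average differed less between arrays than either feature did, with an SD of 0.21. The insulin-like growth factor binding protein gene igfbp1a had 0.80 and agxta, a paralogue of agxtb, -0.996. Leaving out replicate 1 gave the liver list an adjusted p of 0.228, and leaving out replicate 2 one of 0.201. The list of inflammation and innate immunity had a median of 0.33 over 15 members, 10 positive (camera adjusted p = 0.0483, and adjusted p = 0.831 with an estimated correlation), with mmp9, a matrix metalloproteinase, at 0.99 and ptgs2a, a prostaglandin synthase, at 0.88. The leukocyte gene lcp1 went the other way, with -0.77 and a negative value on every array. Its medians were 0.33, -0.02 and 0.49 on the 3 arrays, and it had an adjusted p of 0.343 without replicate 1 and of 0.0592 after centring. The erythroid list had a median of 0.10 over 16 members, 10 positive (camera adjusted p = 0.0499, and adjusted p = 0.831 with an estimated correlation). Adjusted over the list alone hbbe3 and hemgn passed, both positive. The erythroid medians were -0.80, 1.04 and 0.54 on the 3 arrays, and the adjusted p was 0.896 without replicate 2, 0.239 without replicate 3 and 0.0592 after centring.

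**Figure D3:**
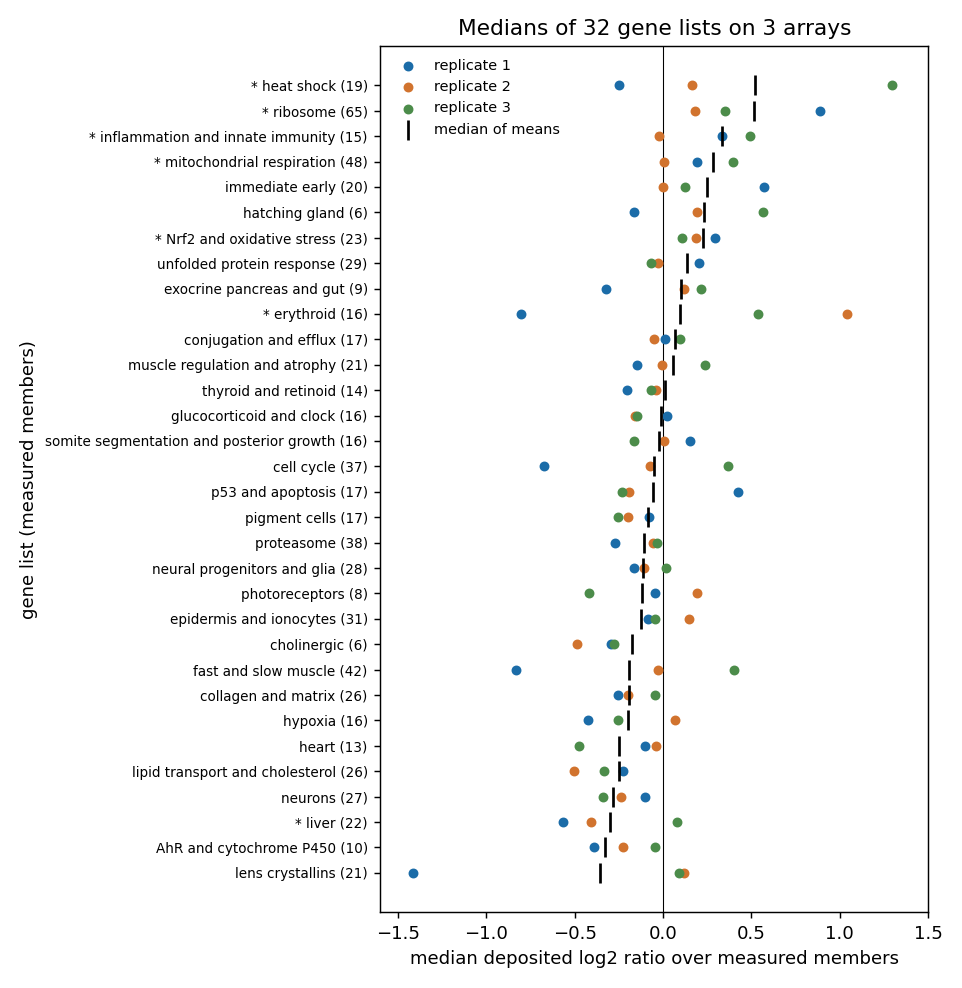
Median deposited log2 ratio (x axis) of the measured members of 32 gene lists (y axis, number of members in brackets), with 1 coloured point per array and a black bar for the median of the members' 3-array means. Stars mark the 7 lists past adjusted p 0.05 in camera with the preset correlation. The ribosome medians are 0.89, 0.18 and 0.35, and those of lens crystallins run from -1.42 to 0.12.

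The other 25 lists did not pass, the smallest adjusted p among them being 0.0711. Of the neuronal genes, 22 of 27 were negative (median -0.28), among them the synaptic gene snap25a at -0.72, and this list passed without replicate 1 (camera adjusted p = 0.0449, and 0.871 with an estimated correlation) and after centring and scaling (camera adjusted p = 0.0420, and 0.813). Of the lipid transport and cholesterol genes 16 of 26 were negative (median -0.25), and lss passed adjusted over the list alone. The list itself passed without replicate 3 (camera adjusted p = 0.0455, and 0.772 with an estimated correlation) and after centring and scaling (camera adjusted p = 0.0420, and 0.813). The cholinergic list had 6 measured members with a median of -0.18. Its member rapsn, which clusters acetylcholine receptors at the neuromuscular junction, passed adjusted over the list alone with a mean of -1.02 ± 0.45 (SD, n = 3), and the acetylcholine receptor subunit chrne had -0.78. In the list of AhR targets and cytochromes P450 the median was -0.33 and the mean 0.03 over 10 members, which differ in sign. Adjusted over that list alone cyp1a passed as positive, and cyp26a1, which degrades retinoic acid, passed as negative at -1.53 ± 1.03 (SD, n = 3). Over the list of thyroid and retinoid genes (median 0.01, mean -0.14) cyp26a1 passed too, with dhrs3b, a retinaldehyde reductase, at -1.22 ± 0.29 (SD, n = 3). Of 16 hypoxia genes (median -0.20), 5 passed adjusted over the list alone. The negative ones were pfkfb4b, pfkfb3 at -0.95 and p4ha1b, a collagen prolyl hydroxylase subunit, at -1.29, and the positive ones were the hexokinase gene hk2 at 1.17 and igfbp1a. The values of hk2 were 0.54, 0.72 and 2.26 on the 3 arrays. In the glucocorticoid and clock list (median -0.01) fkbp5 passed adjusted over the list alone, and tsc22d3, another glucocorticoid-induced gene, had -0.90, while the clock gene cry2 had 1.04 and pomca, which encodes the precursor of corticotropin, 0.91. In the immediate early list (median 0.25) klf11a passed as negative, while fosab had 2.89 ± 2.498 (SD, n = 3), with 5.64, 0.77 and 2.26 on the 3 arrays. Without replicate 1 the mean of fosab was 1.51, and without replicate 2 it was 3.95 and passed (limma adjusted p = 0.0261), again on mostly pooled variance. The list passed as positive without replicate 2 (camera adjusted p = 0.0388, and 0.983 with an estimated correlation). In the unfolded protein response list (median 0.13) atf6 passed at 1.19 ± 0.24 (SD, n = 3).

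Most of the remaining lists held markers of tissues. Lens crystallins had -0.36, with -1.42 on array 1 and 0.12 and 0.09 on arrays 2 and 3. Fast and slow muscle had -0.19 over 42 members, with -0.83, -0.03 and 0.40 on the 3 arrays, and cell cycle genes had -0.05 over 37 members, with -0.67, -0.07 and 0.37. These 3 lists passed as negative without replicate 3, with camera adjusted p of 0.000961 for lens, 0.000255 for muscle and 0.00122 for cell cycle. With an estimated correlation, at 1, 0.310 and 0.694 in that order, each had an adjusted p = 0.772 there. The medians were -0.25 for heart, -0.19 for collagen and matrix, -0.13 for epidermis and ionocytes, -0.12 for photoreceptors, -0.11 for neural progenitors and glia, -0.11 for the proteasome and -0.09 for pigment cells. They were -0.06 for p53 and apoptosis, -0.02 for somite segmentation and posterior growth, 0.06 for muscle regulation and atrophy, 0.07 for conjugation and efflux, 0.10 for exocrine pancreas and gut and 0.23 for the hatching gland. The signs of the photoreceptor, glucocorticoid, p53, cell cycle and somite medians changed under at least 1 of the other scalings. In 5 of the 32 lists the median, the mean and the camera test did not share 1 sign.

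The values of agxtb rest on 1 of its 2 features and those of cyp1a on 1 of 3, and the call of agxtb was lost without replicate 1 (mean -4.18, limma adjusted p = 0.219) and after centring and scaling (mean -4.63, limma adjusted p = 0.153), where cyp1a was the 1 gene that passed. The mean of agxtb stayed near the -4.36 of the main setting in both. The values of gc, rhcga and dennd2db also rest on 1 of 2 features each. Near-identical gene copies such as globins, crystallins and heat shock genes are uncertain where probes do not separate them, and the 827 genes at an unadjusted p under 0.05 hold no correction for the number of tests.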

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

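All tests in this part were chosen after the values were seen, apart from the count over sign patterns of the arrays.

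Features at the corners of the array grid carry no gene name and entered no test but that of all 13895 features, named or not. Their median log2 ratio over 9 features was -0.07 on array 1, but 2.401 on array 2 and 3.99 on array 3, above 99.9% of named features on each of those 2 arrays. This drew attention as a signal outside the measured genes. Over the whole array 177 features lay near 0 on array 1 and between 2 and 3 on array 2. Of these 0 carried a gene name under the order used, against 78 under the deposited numbers. No explanation was tested for it.

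The row numbers drew attention because features of the same gene did not share values. Under the reading of the deposited numbers as feature numbers the mean correlation of same-gene pairs was -0.00811, which argues against that reading. Under the reading by columns of the rotated grid it was 0.568, a value that no other of the 42 orders approached. The order may still be wrong for single features, which a same-gene test over 1420 pairs would not show. No biological explanation was tested.

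The positive values of ribosomal protein genes (median 0.52) can be set against 3 technical explanations. One array alone is argued against, since on each array by itself the list lay above all genes, by 1.02, 0.20 and 0.40. The second highest lower bound of a 95% bootstrap over its members was 0.289. Like the intervals below, it treats members as independent, though their estimated correlation was 0.087, so it is likely too narrow. It does not measure variation between arrays. Camera does not settle the question of 1 array alone. After leaving out 1 array its largest p was 3.48e-08 at the preset correlation. With an estimated correlation, a test of little power on so few arrays, the largest camera p was 0.218, and on all 3 arrays it was 0.0584. Abundant mRNAs in general are argued against only as far as a set of 42 genes outside the ribosome stands for them, since abundance was not measured. The set had a median of -0.25, with a 95% bootstrap interval of -0.30 to -0.07. That lies below 0.26, which is 0.5 of the ribosome median. Its medians were -0.69, -0.01 and -0.04 on the 3 arrays, so the negative value came mostly from array 1. Short mRNAs in general stay open and met their test, with a median of 0.41 over 61 genes and an interval of 0.29 to 0.52, so a bias of RNA quality or labelling toward short transcripts is a candidate explanation. An effect of the exposure on these genes stays open as well, untested, because transcript length and gene function were not separated here. An effect of the dyes was not tested either.

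Turning the sign of 1 array at a time gives 4 patterns of the 3 arrays, the real one included, which is too few for a share under 0.05. The real arrays gave 6 features, 1 gene and 1 gene past 2-fold, and the highest of the other patterns gave 0 for each, so 1 of the 4 patterns reached these counts. For genes at least 2-fold the same way on every array the real count was 21 and the highest other 6, again 1 of the 4. For gene lists the real count was 7 and the highest other was also 7, and 3 of the 4 patterns reached it.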

How the results depend on the processing

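No paired analysis was possible because each array's ratio is itself the pair of exposed and control RNA. The settings named "by deposited row number" and "all features" were chosen after seeing the data; the others were planned. The cause of each change was not tested unless given.

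Features past adjusted p 0.05 numbered 6. There were 1 after centring (0 positive), 1 after centring and scaling (1 positive), 3 after quantile normalization, 1 with a value on at least 2 arrays, 0 with the ordinary one-sample test, 0 by deposited row number and 0 over all features. Leaving out 1 array gave 0 to 88, the 0 without replicate 1, with 82 without replicate 2. Genes past adjusted p 0.05, and those past 2-fold as well, numbered 1. There were 6 after quantile normalization, 6 with robust variance, 6 at adjusted p 0.1, 0 with the ordinary test (547 at an unadjusted p under 0.05), 0 with the feature of smallest variance and 0 by deposited row number. Without 1 array they numbered 0 to 13, the 0 without replicate 1, with 5 without replicate 2. Genes 2-fold the same way on every array numbered 21, with 32 after quantile normalization, 34 with a value on at least 2 arrays and 16 by deposited row number (6 positive and 10 negative). With 1 array fewer to meet the rule they numbered 55 to 144. Gene lists past 0.05 numbered 7, with 4 on ranks, 0 by deposited row number and 5 to 9 without 1 array. Under an estimated correlation, which leaves few degrees of freedom on 3 arrays, there were 0.

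Among 138 named genes under 6 settings, 810 of 828 values kept their sign and side of the threshold. The sign reversed without replicate 3 for chrna1 (-0.002415 to 0.553 without 1 array) and he1.1 (-0.0562 to 1.02). No feature was listed at exactly 0 and no array correlated below -0.3 with the others, so those planned settings changed nothing. Over 8 settings the adjusted p of the ribosome list ran from 3.93e-15 to 0.831 and that of mitochondrial respiration from 0.000103 to 0.831, each past 0.05 in 7. It ran from 0.00409 to 0.831 for Nrf2 and from 0.00013 to 0.831 for heat shock, each past in 6. For liver it ran from 0.000288 to 0.831 (past in 4), for inflammation from 0.0184 to 0.831 and for erythroid from 2.58e-07 to 0.896 (each past in 3). Over 6 settings agxtb ran from 3.33e-06 to 0.219 (past in 4) and cyp1a from 0.00159 to 0.301 (past in 3). Signal over background is unknown.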

Other observations

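The gene families and tests in this part were chosen after their values were seen. Several families share genes with the lists above and are no separate support for those lists. Patterning genes of the hox clusters leaned one way: of 31 measured hox genes 25 had negative means and 20 were negative on all 3 arrays, with a median of -0.45 (camera p = 8.28e-05 at the preset correlation and p = 0.0462 with an estimated one). The median stayed between -0.38 and -0.46 under the other scalings. The 4 measured genes of paralogue group 5, hoxa5a, hoxb5a, hoxb5b and hoxc5a, lay between -0.87 and -1.11. The posterior gene hoxc13a went the other way at 0.76. None of the 31 passed over all genes in limma, and 10 had an unadjusted p under 0.05. In the retinoic acid pathway, which sets hox expression along the trunk, cyp26a1 had -1.53, dhrs3b -1.22 and rdh1 -1.17, while rdh10b, which makes retinaldehyde, had 0.60. The other 3 genes of that set were cyp26b1 at -0.48, cyp26c1 at -0.02 and aldh1a2 at 0.09. Over the 7 genes the median was -0.48, and the camera p was 0.031 at the preset correlation and 0.156 with an estimated one.

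All 12 measured genes of coagulation factors and their regulators had negative means, 9 of them on all 3 arrays, with a median of -0.57 (camera p = 8.90e-06 at the preset correlation and p = 0.0695 with an estimated one). Most of the 12, f2 and f10 among them, also belong to the liver list. In this set f2, f5 and f7i had -1.34, -1.003 and -1.24, while f10 and f7l had -0.07 each, with both signs among their arrays. Of 16 genes of cholesterol synthesis and its control, 13 were negative, with a median of -0.52 (camera p = 0.000296, and p = 0.138 with an estimated correlation). They include lss at -1.40, insig1 at -0.99 and cyp51 at -0.81. Most of the 16, these included, also belong to the lipid transport and cholesterol list. The ammonium transporter genes rhcga and rhbg had -2.27 and -1.53. Globins split by array: of 6 genes, hbbe3 and hbae4 were positive on all 3 arrays, while the globin median was -1.18 on array 1, 1.24 on array 2 and 0.71 on array 3.

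A hypothesis is that positive values stand for higher levels in exposed embryos, since chemical exposure commonly raises AhR, conjugation, Nrf2 and heat shock genes. Over the 69 measured genes of these 4 lists 42 were positive, with a median of 0.22. The 4 lists did not agree: the medians were 0.22 for Nrf2 and 0.52 for heat shock, which were seen to be positive before they were combined, 0.07 for conjugation and -0.33 for AhR, and the heat shock median was -0.25 on array 1. The camera p was 0.00118 at the preset correlation and 0.113 with an estimated one, so the test leaves the direction open. The mean of cyp1a, at 3.57, would be a rise under this direction, and those of ahr2 (-0.79) and cyp1c1 (-0.64) a fall.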
